A study of Mus musculus with 24 samples.

How the data were processed

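Single cells of the mouse strain C57/Bl6J were profiled by Smart-seq2, a plate-based method that copies polyadenylated RNA along its length and amplifies it by PCR without molecular identifiers. Per the labels' protocols, fetal liver was taken at embryonic day 14.5, red cells were lysed, and cells carrying CD3e, CD45R, Ly-6G, CD11b, Ter119, Sca-1, CD16/32 or CD41 were depleted with magnetic beads. The remaining cells were stained for CD117, CD71 and CD24 and sorted into wells, and libraries were made with a tagmentation kit and sequenced without strand information. The gate boundaries are not given in the sources used here.

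The deposited table holds raw read counts per gene, 1 column for each of 24 cells, and the authors' counts were used as deposited. STAR 2.4, featureCounts and the genome build GRCm38 are named in the submitters' processing notes. The annotation release, the counting options and any filter on cells are not given in the sources used here. Every row of the table is an Ensembl mouse gene, and 49326 of the 49585 identifiers matched a symbol in GENCODE M21, which is also built on GRCm38 and gave the coordinates. The 259 unmatched identifiers hold 0.0295% of all counts. Each column name matched the well in the description of a single cell. Cells are numbered as in their titles, BFU-E 1 to 24, in wells that span 3 plate columns of 8 cells.

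All 24 cells belong to 1 group and no embryo is named for any cell. A cell is not a replicate animal, so the group counts as 1 sample. No p-value or standard error was made from cells, and the count of genes along the axis describes these cells only. The spread over the 24 cells is given as SD and range. Correlations across cells describe these 24 cells, and each is set against 10000 random gene lists, or pairs of lists, matched on mean expression (2000 where a single cell is left out). The percentile is the share of random lists at or under the observed value. It takes cells as the units, so it says nothing of other embryos.

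Counts were scaled to CPM by the total over all gene rows of a cell. A gene was called detected in a cell at 5 counts or more. Analyses across genes used 8266 genes detected in at least 6 cells, on the log2(CPM + 1) scale, and genes were ranked along the axis only if detected in at least 12 cells, which left 5962. The score of a list in a cell is the mean over its genes of log2(CPM + 1) minus the mean of all genes in the same bin of mean expression, with 20 bins. Genes shared by a pair of lists were left out of both. The axis is the maturation score minus the early score, and a list member was left out of the axis it was compared with. Co-variation is the mean Spearman rho over all gene pairs of a list with at least 4 genes kept. Variable genes were ranked by the variance of log2(CPM + 1) minus a lowess trend on the mean, with a span of 0.3. Principal components used the top 500 of these genes, and 100 shuffles of each gene across cells served as reference.

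The 28 gene lists, the score, the thresholds and the naming rule were fixed before the data were examined. The rule names the 3 highest members of each list by mean CPM, a fixed set of progenitor, erythroid, cell cycle, sort and other-lineage genes, the 10 genes of largest variance residual, the 5 genes at each end of the axis outside its lists, and the 10 most abundant genes. Predicted models, pseudogenes and identifiers without a symbol were passed over in the last 3 parts. Other genes named below were chosen after their values were seen, and so was the threshold of 10 CPM for Klf1. The symbols Hbb-b1, Hbb-b2, Ahsp and Ly76 were not matched to a row and are not analysed here. Some genes that the rule names are not reported here.

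Total counts ran from 876983 to 2155010 per cell. A count of 0 allows up to 3 counts, which is 1.39 to 3.42 CPM depending on the cell. The share of cells with Gata1 or Klf1 carries an exact binomial 95% interval, which takes the cells as independent draws and says nothing of other embryos. The interval and the floors cover counting error only, and PCR copies are not independent molecules. Reads are spread along transcripts, so levels of different genes also depend on transcript length. Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies whose reads the counting could split or lose, and their values are uncertain. Reads of overlapping or antisense genes, Xist and Tsix among them, cannot be told apart without strand.

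The statistics were tested on simulated cells before use, with 200 seeded genes. In the simulation of genes along the axis, over 5918 genes, 49.3% of genes given a log2 slope of 2 per SD of the axis passed an absolute rho of 0.6, 26.6% at a slope of 1 and 8.62% at a slope of 0.5, against 0.299% of unseeded genes. In that of variable genes, over 10720 genes, 86.7% of genes given an extra SD of 1 on the log2 scale ranked among the top 200. The other genes there had a smooth spread with an SD of 0.5 on the log2 scale. Many genes in these cells spread more widely, so that share does not measure how well such genes are found here. In that of co-variation, 2% of 200 unrelated lists came within the top 2.5% of matched random lists.

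The alternatives were TMM, DESeq2 and scran scaling, a total without mitochondrial and globin genes, thinning of every cell to 876983 counts, a pseudocount of 5, other gene filters, Pearson correlation, 10 bins, plain means, plate columns taken separately, other detection thresholds and each cell left out in turn. Leaving out the 5 cells with Klf1 under 10 CPM was added after the data were seen, as was leaving out single cells for means of genes, for list medians along the axis and for pairs of scores. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, figures matplotlib 3.10.9, and size factors R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and scran 1.30.0.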

Results

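The data are transcriptomes of 24 single cells sorted from mouse fetal liver as burst-forming units-erythroid (BFU-E), early progenitors committed to the red cell lineage. There is 1 group and no second condition, so the values describe what these cells expressed and how they differed from each other. Total counts were 1515171 ± 312804 per cell (mean ± SD over 24 cells, as throughout). The number of genes with at least 5 counts had a median of 6089.5 and ran from 4767 to 7349. Mitochondrially encoded genes took 3.55% ± 0.673 of counts and ribosomal protein genes 7.42% ± 0.624.

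The cells carried a progenitor programme and almost no globin, and most of them carried erythroid regulators. Kit, the receptor for stem cell factor and the CD117 antigen of the sort (ENSMUSG00000005672, GRCm38 chromosome 5, 75574916 to 75656722), was detected in 24 of 24 cells at 323 ± 182 CPM. Myb, a transcription factor of blood progenitors, was also in 24 cells at 385 ± 215 CPM, and the adhesion receptor Adgrg1 at 316 ± 211 CPM. Gata2 was detected in 15 cells at 159 ± 322 CPM, or 101 ± 158 without cell 3, and Nr3c1, the glucocorticoid receptor, in 17. Zfp36l2 was found in 21 cells at 30.7 ± 31.5 CPM, and Tgfbr3 in 11. Of the 24 early progenitor genes, 14 were detected in at least 12 cells. Cd34 was detected in 5 cells only, at up to 1554 CPM.

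Erythroid regulators were broadly present: 22 of the 26 genes for erythroid transcription and signalling were detected in at least 12 cells. Gata1, the master regulator of erythroid genes (ENSMUSG00000031162, chromosome X, 7959260 to 7978071), and Klf1, which activates globin and membrane genes (ENSMUSG00000054191, chromosome 8, 84901928 to 84905291), were each detected in 20 of 24 cells (83.3%, exact binomial 95% interval 62.6 to 95.3). Their levels were 344 ± 214 and 414 ± 308 CPM. The erythropoietin receptor Epor was in 18 cells at 134 ± 119 CPM, Lmo2 in 22 and Myc in 24, the last at 845 ± 447 CPM.

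Genes of later red cell maturation were thinner, with 13 of 36 measured members in at least 12 cells. Carbonic anhydrase Car2 was in all 24 cells at 812 ± 475 CPM and Car1 in 19, at 558 ± 1139 CPM with a maximum of 5252 in cell 12, or 354 ± 557 without that cell. The anion exchanger Slc4a1 reached 5 counts in 0 cells. The 4 adult globin genes measured took at most 0.00855% of a cell's counts: Hba-a1 averaged 4.39 ± 7.25 CPM, Hba-a2 0.465 ± 1.22, Hbb-bs 2.4 ± 5.26 and Hbb-bt 5.90 ± 17.1, all uncertain because of their near-identical copies. Hbb-bt rests on cell 23, without which it averaged 2.54 ± 4.59, and Hba-a2 averaged 0.282 ± 0.852 without cell 5. The 4 embryonic globin genes, Hbb-y, Hbb-bh1 and Hba-x among them, had 0 counts in every cell, which allows up to 3.42 CPM in the shallowest.

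Of 25 haem and iron genes 21 were detected in at least 12 cells, led by the ferritin genes Fth1 at 1247 ± 383 and Ftl1 at 915 ± 249 CPM and the mitochondrial membrane gene Tmem14c at 564 ± 343 CPM. Alas2, the erythroid form of the enzyme that starts haem synthesis, was detected in 2 cells, while its housekeeping counterpart Alas1 was in 18.

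Growth and division genes were abundant. All 36 genes of S phase and 33 of 36 genes of G2 and M phase were detected in at least 12 cells. Mcm6, part of the replicative helicase, stood at 1151 ± 472 CPM, Mcm3 at 701 ± 270, Mcm7 at 683 ± 278 and Pcna at 515 ± 184. Hmgb2 stood at 614 ± 192, Ccnb2 at 370 ± 308 and Cdc20 at 358 ± 340 CPM. Mki67 was detected in 21 cells and Cdk1 in 20. Of 18 genes for cell cycle inhibition and quiescence 5 were so detected, with Trp53 at 603 ± 158, E2f4 at 191 ± 117 and Ccng1 at 78.1 ± 58.7 CPM. All 30 genes of ribosome biogenesis and translation, all 27 nuclear genes of mitochondrial respiration and all 18 of glycolysis were detected in at least 12 cells. Their leading members were Eef1a1 at 7260 ± 1497, Npm1 at 3876 ± 948 and Ncl at 2133 ± 606; Atp5b at 3181 ± 736, Atp5a1 at 1686 ± 374 and Cox4i1 at 1153 ± 156; and Ldha at 3681 ± 930, Aldoa at 1417 ± 559 and Tpi1 at 1350 ± 439 CPM.

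The most abundant named gene was the mitochondrial ribosomal RNA mt-Rnr2, at 1.20% ± 0.319 of counts, followed by the elongation factor Eef1a1 at 0.726% ± 0.150, mt-Co1 at 0.685%, mt-Cytb at 0.655%, mt-Nd1 at 0.549%, Actb at 0.530%, Hsp90ab1 at 0.465%, Rpl4 at 0.429%, Rplp0 at 0.425% and Eif5a at 0.402%. A row annotated as ribosomal RNA and passed over by the naming rule, CT010467.1 (chromosome 17, 39846353 to 39848827), took more, at 5.41% ± 0.888. It was singled out after its values were seen.

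Glucocorticoid response genes were sparse, with 6 of 19 in at least 12 cells, led by Txnip at 111 ± 112, Sesn1 at 96.4 ± 124 and Fkbp5 at 58.2 ± 72.1 CPM. Of 23 immediate early and stress genes 6 were so detected. The chaperone genes Hspa8 and Hsph1 stood at 3152 ± 1331 and 213 ± 156 CPM and Atf4 at 138 ± 90.6, while Fos reached 5 counts in 0 cells. Among 27 cytokine receptor genes 6 were so detected, with Kit, Ifngr1 at 292 ± 223 and Epor leading.

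The antigens of the sort could be compared with their transcripts. Of the 3 gated antigens, Kit was in 24 cells, Tfrc, which encodes CD71, in 18 at 59.5 ± 63.6 CPM and Cd24a in 15 at 111 ± 158 CPM. Of 9 measured genes listed for depleted antigens, 2 were detected in at least 12 cells and 4 in none. Itga2b, which encodes CD41, was in 16 cells at 117 ± 148 CPM. Ptprc was in 11 at 47.1 ± 91.9, counted over every isoform, while the depleted CD45R is one of them. The list also held Ly6e, which encodes none of the depleted antigens and was in 21 cells at 277 ± 280 CPM. Transcript levels say nothing of surface protein. Of 15 surface proteins that mark erythroid progression, 13 were so detected, with Cd47 at 618 ± 391 and Bsg at 415 ± 90.6 CPM.

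The score of the early progenitor list fell as that of the erythroid maturation list rose, with Spearman rho −0.57 and Pearson r −0.54 over 24 cells. That rho lay at the 0.17th percentile of 10000 pairs of matched random lists. Without the 2 cells farthest from the median early score r was −0.57. For the pairs below, the 2 cells are those farthest from the median of the score that is neither early nor maturation. For the pair of cell cycle scores it is the S phase score, so the 2 cells can differ between pairs. Within plate columns 1, 2 and 3, with 8 cells each and genes and scores fitted anew, rho was −0.26, −0.52 and −0.31. These lay at the 26.1st, 9.99th and 21.9th percentiles, so no column alone separated the relation from random lists. With the scores of all 24 cells rho was −0.43, −0.43 and −0.26. Median early scores of the columns were 0.28, −0.74 and 0.016, and median maturation scores −0.86, 0.80 and 0.015. Haem and iron genes followed maturation (rho 0.71, r 0.76, 99.98th percentile; r 0.67 without 2 cells). Without 5 cells with Klf1 under 10 CPM that rho was 0.43 and r 0.48, at the 96.7th percentile, inside the central 95% of random pairs. Against the early score haem and iron genes lay inside it over all 24 cells (rho −0.37, r −0.41, 4th percentile; r −0.51 without 2 cells), and outside it when cell 1, 4, 18 or 22 was left out singly, at the 1.5th to 2.4th percentile. Ribosome biogenesis ran against the early score (rho −0.54, r −0.54, 0.39th percentile; r −0.45 without 2 cells) and not with maturation (rho 0.090, r 0.098, 65.4th percentile; r −0.16 without 2 cells).

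**Figure D1:**
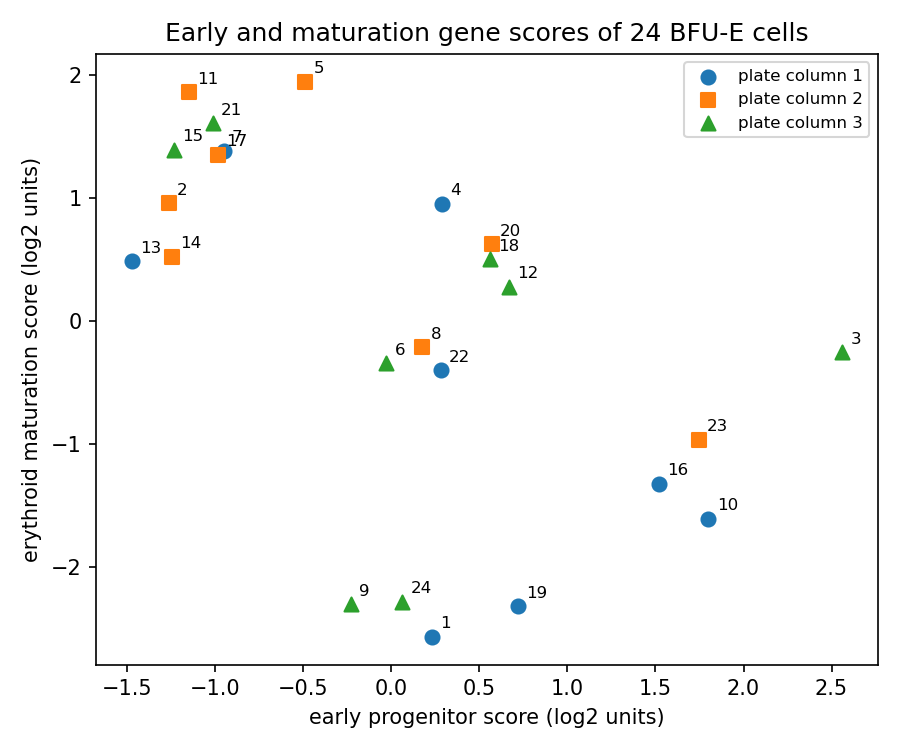
Early progenitor score (x axis, log2 units) against erythroid maturation score (y axis, log2 units); each point is a cell with its number, and its shape gives the plate column. The scores fall against each other with rho −0.57, and cells 1, 9, 19 and 24 lie lowest in maturation.

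Erythroid transcription and signalling rose with the maturation score (rho 0.50, r 0.71, 99.1st percentile; r 0.60 without 2 cells) and lay within random pairs against the early score (rho −0.13, r −0.071, 28.1st percentile; r −0.15 without 2 cells). Without the 5 cells low in Klf1 the relation with maturation had rho −0.005 and r −0.068, and r 0.29 with 2 further cells left out. Klf1 belongs to this list, so picking cells by Klf1 also narrows the list's score. The fall may partly follow from that choice. S phase against the early and maturation scores gave rho −0.19 and 0.24 (r −0.24 and 0.18), G2 and M phase −0.003 and 0.20 (r 0.046 and 0.20), and the glucocorticoid response −0.073 and 0.094 (r −0.063 and 0.17), all inside the central 95% of random pairs. S phase and G2 and M phase scores fell against each other (rho −0.49, r −0.57, 1.06th percentile; r −0.60 without 2 cells). These are 14 relations between scores, and apart from the leading relation none was recomputed within plate columns.

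Along the axis of maturation minus early score, 141 of 5962 genes had an absolute rho of at least 0.6, of which 87 rose and 54 fell. This count, and the list medians below, take no account of plate column, although the median scores differed between columns. Among 100 axes made from random list pairs the median was 16 genes and the maximum 79. The random lists were matched on mean expression and not on co-variation, which both axis lists show. The higher count is thus no separate evidence for an order of maturation. The genes that rose most outside the axis lists were Tnfaip2 (rho 0.87), the superoxide dismutase Sod1 (0.81), Ifi30 (0.80), Ptdss2 (0.80) and Cpox, an enzyme of haem synthesis (0.77). Sod1 averaged 1058 ± 323 CPM and Tnfaip2 133 ± 135. Those that fell most were Laptm5, a lysosomal membrane gene of blood cells (−0.82), the actin regulator Coro1a (−0.80), Rasal3 (−0.78), Grcc10 (−0.77) and Ptpn18 (−0.77). Laptm5 averaged 419 ± 437 and Coro1a 476 ± 743 CPM. Without the 5 cells low in Klf1, 122 of 5067 genes passed, against a median of 40 for random axes, and 36 of the rising and 23 of the falling genes were shared.

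Some lists had a median rho along this axis outside the central 95% of matched random lists. Those random lists were again matched on mean expression and not on co-variation. Genes of several of these lists varied together, with a mean pairwise rho of 0.24 for megakaryocyte and 0.22 for myeloid genes. A median over such genes spreads more widely than one over unrelated genes, so the percentiles below can overstate the departure. The median rho of the haem and iron genes outside the axis lists was 0.35 (100th percentile), of nuclear genes of mitochondrial respiration 0.29 (99.4th) and of ribosome biogenesis 0.23 (98.3rd). Megakaryocyte, myeloid, stem cell and hepatocyte genes had medians of −0.32, −0.47, −0.50 and −0.40, all at or under the 0.09th percentile, from the 9, 7, 5 and 5 genes of each list that were kept. The megakaryocyte median was −0.20 without cell 16, and stayed at or under the 1.4th percentile whichever single cell was left out. Cell 10, which carried by far the most hepatocyte transcripts, had the lowest axis value, and without it the hepatocyte median was −0.40 (0.2nd percentile) from 4 genes. Ribosome biogenesis fell inside the central 95% of random lists when any of 8 cells was left out singly, down to 0.17 (87.4th) without cell 3, and mitochondrial respiration without cell 11 (0.24, 95.5th) or cell 17 (0.25, 97.0th). S phase came to lie above the central 95% when any of 5 cells was left out, erythroid transcription when any of 4 was and glycolysis without cell 1, while quiescence without cell 5, cytokine receptors without cell 10 and surface progression without cell 11 came to lie under it. Without the 5 cells low in Klf1, mitochondrial respiration stood at 0.20 (95.1st) and ribosome biogenesis at 0.18 (96.0th), inside the central 95% of random lists, and S phase went from 0.18 (96.0th) to 0.22 (99.8th). Haem and iron genes stood at 0.22 (99.3rd) and megakaryocyte, myeloid and stem cell genes at −0.45, −0.34 and −0.45, at or under the 0.5th percentile, while hepatocyte genes were too few.

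**Figure D2:**
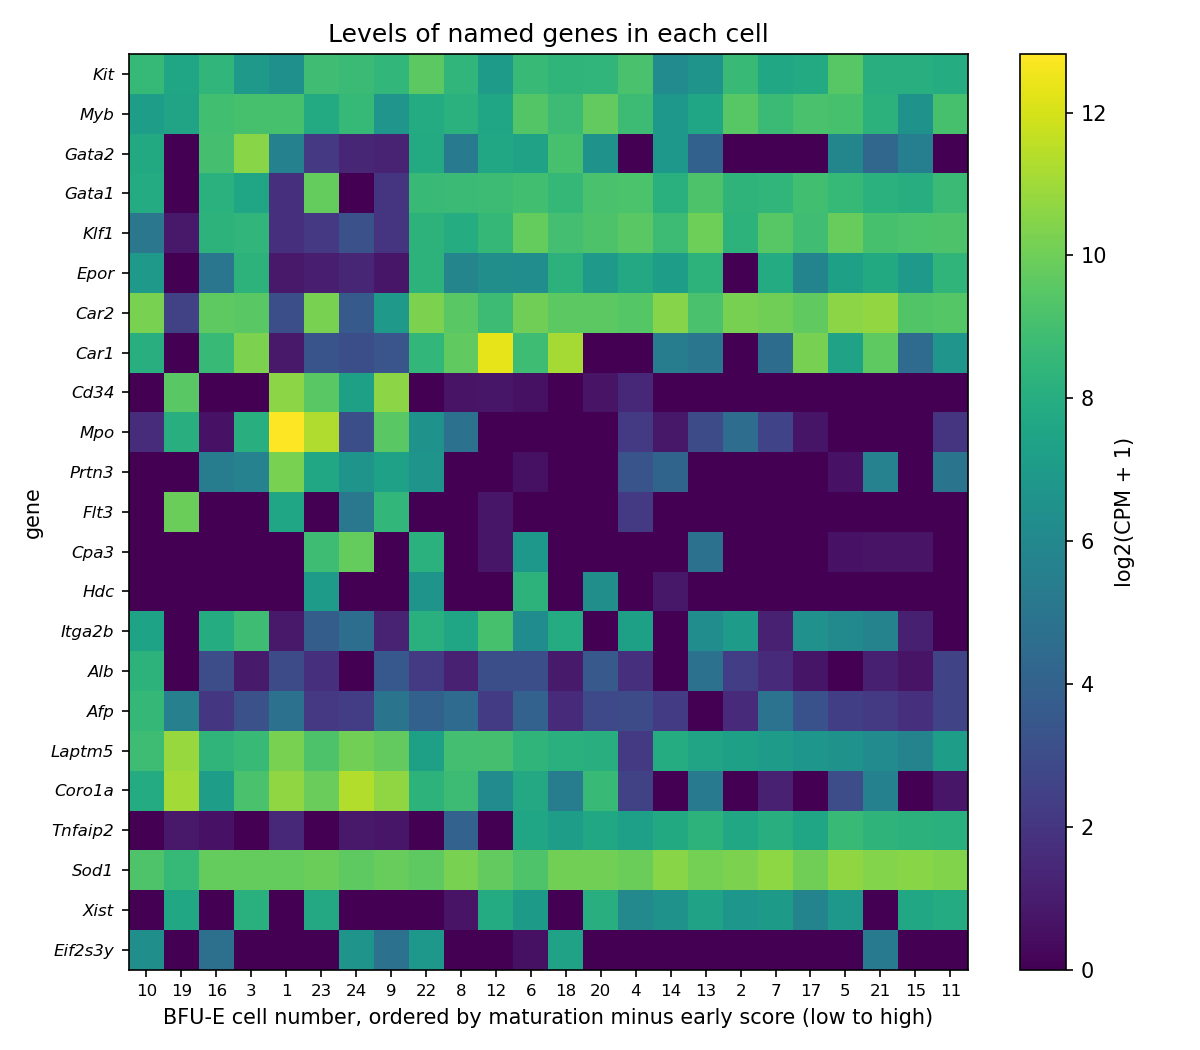
Level of a chosen part of the named genes (rows, log2(CPM + 1) as colour) in each of the 24 cells (columns, ordered from low to high maturation minus early score). Klf1 is under 10 CPM in cells 1, 9, 19, 23 and 24, where Cd34 is detected, and Tnfaip2 is high towards the right.

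Genes of a list tended to vary together from cell to cell for 11 of the 19 lists with enough genes. The mean pairwise rho was 0.25 for G2 and M phase, 0.23 for erythroid maturation, 0.24 for megakaryocyte genes, 0.22 for myeloid genes, 0.14 for S phase, 0.12 for glycolysis, 0.12 for ribosome biogenesis and 0.11 for early progenitor genes. Erythroid transcription gave 0.092, mitochondrial respiration 0.080 and haem and iron 0.078. All 11 lay within the top 2.5% of matched random lists. The size could rest on 1 cell: megakaryocyte genes gave 0.16 without cell 12, myeloid genes 0.37 without cell 9 and glycolysis 0.073 without cell 19. These 3 lists stayed within the top 2.5% whichever single cell was left out. Hepatocyte genes (0.15), stem cell genes (0.11), quiescence (0.027) and glucocorticoid response genes (0.008) lay under that level, and stress (−0.037), the list of depleted antigens with Ly6e (−0.066), surface progression (−0.023) and cytokine receptors (−0.044, 1.49th percentile) were below 0. Without the 5 cells low in Klf1, erythroid transcription fell to −0.007 (28.9th percentile), mitochondrial respiration to 0.008 (55.9th) and myeloid genes, of which 4 were kept, to 0.18 (95.4th), and cytokine receptors stood at −0.058 (4.35th). Klf1 is in the erythroid transcription list, so the fall of that list may partly follow from picking cells by Klf1. Without cell 19 alone mitochondrial respiration was at 0.028 (86.8th), and cytokine receptors rose above the 2.5th percentile when any of 5 cells was left out singly. Hepatocyte genes came within the top 2.5% when any of 11 cells was left out, and stood at 0.044 (66th) without cell 10.

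The most variable named genes were Coro1a, Car1, Apoe, Lcp1, Blvrb, Mpo, Klf1, Gata1, Tnfaip2 and Mfsd2b. Apoe ranged from 0.810 to 4398 CPM, Lcp1 from 0 to 1096, Blvrb, a biliverdin reductase, from 0 to 740 and Mfsd2b from 0 to 1170. The main direction of variation over the top 500 genes held 17.8% of variance, against 5.83 to 6.52% in 100 shuffles. The shuffles remove all co-variation, so any difference that genes share between cells would exceed them. This direction followed the maturation score (rho 0.87), ran against the myeloid score (−0.85) and was also related to total counts (0.58) and genes detected (0.45). The cells low in Klf1 had its lowest values: −0.596 in cell 19, −0.312 in 23, −0.305 in 24, −0.295 in 9 and −0.239 in 1. It thus largely set those cells apart from the rest.

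Transcripts of other lineages were found in many cells. At least 3 members at 10 CPM were found in 21 cells for megakaryocyte genes, 14 for myeloid, 13 for stem cell, 4 for macrophage, 3 each for mast cell and basophil, lymphoid and hepatocyte genes, and 0 for endothelial and stromal genes. At 50 CPM, 16 cells had at least 3 megakaryocyte genes. F2r was in 22 cells at 233 ± 223 CPM, while the platelet factor gene Pf4 had 0 counts in every cell. Cells 16 and 12 carried 15 and 12 megakaryocyte genes at 10 CPM. Mpo, which encodes myeloperoxidase, was in 12 cells, with 7227 CPM in cell 1 and 2507 in cell 23; Cst7 averaged 82.9 ± 150 and Prtn3 81.1 ± 243 CPM, the latter 32.8 ± 55.6 without cell 1. Srgn was in all 24 cells at 474 ± 477 CPM, Cpa3 in 5 cells and Hdc in 4. Flt3 was in 5 cells, Nkg7 in 6 and Ccl5 in 1. Ifitm1 averaged 55.3 ± 109 and Angpt1 45.1 ± 98.5 CPM, the latter 27.0 ± 44.6 without cell 23. Alb was in 10 cells and Afp in 19, with 316 and 376 CPM in cell 10, and Apoa2 in 4. Ctsb was in 19 cells, Slc40a1 in 12, Lyz2 in 6, Pecam1 in 9, Pdgfrb in 3 and Col1a2 in 2.

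Sex chromosome transcripts separated the cells cleanly. Xist, the RNA of the silenced X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), reached 5 counts in 15 cells, at up to 283 CPM, and Y-linked genes did so in 8 other cells, led by Eif2s3y in 7, Uty in 3 and Ddx3y in 1. Both were found in 0 cells and neither in 1 (cell 1). Tsix, which overlaps Xist on the other strand, reached 5 counts in 2 cells.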

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

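The early and maturation scores kept a negative rho under every alternative run, from −0.72 with no gene filter to −0.26 and −0.31 within plate columns 1 and 3, where 8 cells each leave little precision; leaving out each cell in turn gave −0.62 to −0.51. The number of genes along the axis stayed within 1.5 times of 141 (125 to 177 with a cell left out), and so did the number of co-varying lists (10 to 12). Of 202 values for single lists 29 moved beyond the spread of random lists and 8 changed sign, 4 of them without the 5 cells low in Klf1, an alternative chosen after the data were seen. Of the lists outside the central 95% of random lists 1 changed sign, erythroid transcription at −0.0071 without those cells, where its rho with the maturation score was −0.0053. Klf1, by which those cells were picked, is a member of that list. Of 234 values for named genes along the axis 8 moved and 2 changed sign, both of Mki67. Of the 50 most variable genes, 41 to 47 were kept with a cell left out, 24 without the 5 cells and 14 when ranked by the squared coefficient of variation. The main direction held 11.7% of variance with 2000 genes, 19.8% with a pseudocount of 5 and 11.01% without the 5 cells. Detection at 1 count raised the median genes per cell to 7607.5, and gave 3 cells with both Xist and Y-linked counts. At 50 CPM, cells with at least 3 members numbered 7 for myeloid, 1 for lymphoid, 8 for stem cell, 1 for hepatocyte and 2 for macrophage genes; at 5 counts they numbered 15 for hepatocyte genes. The cause was not tested for any of these. No cell had under 0.5 of the median number of genes, and no spike-in trend was run because the table used has only gene rows. Depth limits calls near 1 count. No paired analysis was possible because there is 1 group.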

Other observations

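All tests in this part but that of depth on the early and maturation scores were chosen after the result was seen. Taken cell by cell, the 5 cells with Klf1 under 10 CPM each carried their own mix of other transcripts, and they were the only cells in which Cd34 reached 5 counts. Cell 1 had Mpo at 7227, Prtn3 at 1192, Irf8 at 670 and Csf1r at 462 CPM, genes of neutrophil and monocyte progenitors, with Gata1 under 3 CPM. Cell 9 had Cd34 at 1554, Mpo at 738, Flt3 at 353 and Hlf at 157 CPM, the last a stem cell gene. Cell 19 had Flt3 at 975, Rag1 at 245, Rag2 at 199, Lck at 191 and Il7r at 169 CPM, genes of lymphoid progenitors. Cell 23 combined Gata1 at 886 and Car2 at 1229 with Mpo at 2507, Cpa3 at 457 and Hdc at 133 CPM. Cell 24 had Cpa3 at 887 and Ccl5 at 573 CPM. Kit was present in each of them, from 84.2 CPM in cell 1 to 465 in cell 23.

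Among all 24 cells, cells 23 and 19 had the fewest genes with at least 5 counts, 4767 and 4800, cell 23 the lowest total and cell 19 the highest mitochondrial share, 4.92%. Poor capture of all genes alike is argued against as the whole cause, though not as a part of it: erythroid genes were missed more often than genes of matched level in each of the 5 cells low in Klf1, at the 99.83rd percentile or above among 10000 lists, for example 38 of 66 genes in cell 9 against a median of 17. A BFU-E may also have shared the well with another cell. The median maturation gene stood at 0.00153, 0.00502 and 0 of its usual level in cells 1, 9 and 19. The lowest of the remaining 19 cells stood at 0.0136. Gata1 was at 2.48, 2.85 and 0 CPM in cells 1, 9 and 19, and at least 187.5 in the remaining 19. By the rule set for it, the test of maturation genes over the 5 cells could not decide. The Gata1 values argue against a BFU-E like the remaining cells as an equal part of the wells of cells 1, 9 and 19. This is weak support, since picking cells by low Klf1 already tends to leave out such shared wells. A smaller part stays open, since the parts of a shared well are unknown. Cells 23 and 24, at 0.0317 and 0.0217, cannot be told apart from a single cell by maturation genes. As low as the upper value were 2 of the remaining 19 cells, and Gata1 was at 886 and 0 CPM. It remains a hypothesis that the gate, with CD34 and FLT3 not among the stained antigens, may have let through CD117-positive cells of other lineages; depletion of CD45R, Ly-6G, CD11b, Sca-1, CD16/32 and CD41 would remove many such cells, the labels name no such group, and no biological explanation was tested.

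Single plate columns, with 8 cells each, did not separate the opposed early and maturation scores from random pairs. Fitted anew within columns 1, 2 and 3, rho lay at the 26.1st, 9.99th and 21.9th percentiles. Over more cells, the opposed scores were not removed by the technical differences that follow. With genes detected and total counts regressed out rho was −0.553, without the 5 cells low in Klf1 −0.551, and with plate column means taken off −0.497, each under the 2.5th percentile of matched random pairs. Both lists were written from textbook knowledge of erythropoiesis. Members of the lists followed the axis unevenly, each left out of its own axis. In the maturation list Blvrb had rho 0.85 and Mt1 0.81, but Car2 had 0.24 and Car1 −0.048. In the early list Adgrg1 had −0.73 and Gata2 −0.33. An ordering of the cells along a stage of maturation is a candidate explanation, and no biological explanation was tested.

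Cell 10 carried 14 hepatocyte genes at 10 CPM, and the 20 genes of that list took 0.205% of its counts. That is 20.5 times the highest share in any other cell, which argues against free liver RNA at a like level in every well. Its Gata1 stood at 237 and Car2 at 1206 CPM. Hepatocyte transcripts at lower levels were not confined to that well, since 15 cells had at least 3 hepatocyte genes at 5 counts. Liver cell material in the well of cell 10 may be the source of its excess, and this was not tested further.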
